A study of Mus musculus with 10 samples.

How the data were processed

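Gene expression was measured in human estrogen receptor positive breast cancer cells grown as xenografts in mice. The mice carried an estrogen pellet, and in the withdrawn groups the pellet was taken out 1 week before the tissue was collected. Per the labels' protocols, tumor cells were taken from frozen sections by laser capture, which cuts chosen cells out of a tissue section under the microscope, and their RNA was amplified by PCR before biotin labelling. The organism field of the labels names the host mouse, while the arrays carry human probe sets, so a probe set can read host RNA only by cross-hybridization. The 10 arrays came from 6 mice and fell into 4 groups. Axillary lymph node metastases were measured in 3 mice with estrogen (mice 6, 11 and 14) and 3 after withdrawal (mice 9, 10 and 19). Primary mammary gland tumors were measured in 2 mice with estrogen (mice 11 and 14) and 2 after withdrawal (mice 10 and 19). The replicate was the mouse, and 4 mice gave both sites.

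The values used were the authors' deposited log2 signal, 1 value per probe set and array, for 61359 probe sets. Per the submitters' processing notes, Partek and RMA, a method that corrects background, normalizes arrays and summarizes probes, were used, and no version of either is given there. The arrays did not share 1 distribution of values, although their medians lay between 2.70 and 2.83. Such a difference in range enters every comparison that sets one of these arrays against another, so each comparison was repeated after quantile normalization between arrays. PCR amplification of small captured samples adds noise and can favor the 3′ ends of transcripts. Arrays give no count, and the number of arrays limits the precision.

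Probe sets were named from the platform's annotation table, in which 44532 had 1 gene symbol and 1492 had several. Another 15273 were unnamed here, and 62 were control probe sets. Genes were taken only from probe sets with 1 symbol. Each of the 19556 genes was represented by the probe set with the highest mean over the 10 arrays. Genes were kept if that mean reached the 25th percentile of all probe set means, a log2 value of 2.311, which removed 2387 genes and left 17169 for testing. Where other probe sets of a gene had a difference of the other sign, the share with the same sign is said beside the gene. Gene symbols are those of the annotation table and can be old.

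Tests used limma 3.58.1 in R 4.3.3 (lmFit and eBayes) with 1 mean per group, all 10 arrays in 1 fit, and mouse as a random block. The consensus correlation within mice was −0.0415, and the prior degrees of freedom were 2.66. Adjusted p-values are from this limma fit with Benjamini-Hochberg adjustment over all genes tested, and a gene was called at an adjusted p below 0.05. There were 7 comparisons: estrogen against withdrawal in each site, the difference between those responses, lymph node against primary tumor with estrogen and after withdrawal, and the averages of the site and of the estrogen comparisons. Differences are on the log2 scale with the standard error (SE) of the fit, and group values are means ± SD. In groups of 2 arrays the SD rests on 2 values.

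The design, the tests, the alternatives other than 3 added ones, and 30 gene lists with 868 genes were fixed before the data were examined. The lists were written from textbook knowledge. They covered estrogen-induced and estrogen-repressed genes, proliferation, metabolism, stress, immune signalling and invasion, and markers of luminal, basal, stromal, immune, fat and muscle cells. Lists were tested with limma's cameraPR, which compares the genes of a list with all other genes, with a preset correlation of 0.01 and adjustment over the 30 lists of a comparison. Each list call was repeated with the correlation estimated from the residuals of the fit.

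Genes were named by a rule. For each comparison it took, of the called genes whose groups did not overlap, the 12 with the most positive and the 12 with the most negative difference. For the difference of responses and the averaged comparisons the call alone was needed. Where fewer than 10 genes were called, the 8 highest and 8 lowest moderated t values were added and are described as not past the threshold. Up to 4 members of each list with the greatest absolute t were also taken, and 12 genes of interest were always reported. Other list members are named from the calls adjusted over the list alone.

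The labels' mouse numbers pair arrays of the 2 sites from the same animal. The correlation of the 2 arrays' deviations from their group means was 0.176 in mouse 10, −0.208 in mouse 11, −0.21 in mouse 14 and 0.0831 in mouse 19, and mouse was kept as a block because the pairing comes from the animal.

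The fits were tested on simulated data with 17169 genes, a seeded set of which was changed by known sizes. In the lymph node comparison 16.2% of the genes changed by 1 log2 unit were recovered, 56.1% of those changed by 2 and 95.5% of those changed by 4. In the primary tumor comparison the shares were 8.82%, 45.5% and 89.4%, and for the average over both sites they were 25%, 75.8% and 100%. Among the unchanged genes of these simulations limma called 3 in lymph nodes, 11 in primary tumors and 5 over both sites. With nothing changed, limma called 0 genes. The simulated noise was normal and independent between genes and arrays, with no mouse effect, difference in range or outlying array. These figures therefore do not cover errors from such features of the real arrays.

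Alternatives were other filters, the mean over a gene's probe sets, quantile normalization, centring of each array, eBayes with a trend and robust option, array weights, fits of only the groups compared, no mouse block, mouse as a fixed block, an unadjusted threshold, and each array left out in turn. The added ones were chosen after seeing the data: quantile normalization without the lymph node array of mouse 11, a covariate for the hybridization control split described with the arrays, and only the lymph node arrays on the low side of that split.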

Results

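Human estrogen receptor positive breast cancer cells were profiled in axillary lymph node metastases and in primary mammary gland tumors of mice that kept an estrogen pellet or had it removed for 1 week. The lymph node groups held 3 mice with estrogen and 3 after withdrawal, and the primary tumor groups held 2 and 2. In 4 of the 6 mice both sites were measured. Each array gave log2 values for 61359 probe sets, from which 17169 genes were tested.

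The 2 arrays of estrogen-treated primary tumors had a narrower range of values than the other 8. Their 99th percentiles were 9.44 in mouse 11 and 10.04 in mouse 14, while those of the other arrays lay between 11.38 and 11.67. The 10 medians lay between 2.70 and 2.83. The first principal component held 50.1% of the variance and set both estrogen-treated primary tumors (87.1 and 93.8) and the estrogen-treated lymph node array of mouse 11 (87.8) apart from the other 7 arrays (−68.3 to 8.36). The 18 hybridization control probe sets split the arrays on another line. Their mean was 12.04 to 12.47 on 4 arrays, namely lymph node mouse 11 with estrogen, lymph node mouse 19 after withdrawal and both withdrawn primary tumors, and 9.47 to 10.59 on the other 6. Between the lymph node groups, array medians (exact two-sided permutation p = 1), 99th percentiles (exact p = 0.6), the GAPDH 3′ minus 5′ difference (exact p = 0.9) and the hybridization controls (exact p = 0.9) did not differ past chance, and 3 against 3 arrays allow no p below 0.1.

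**Figure D1:**
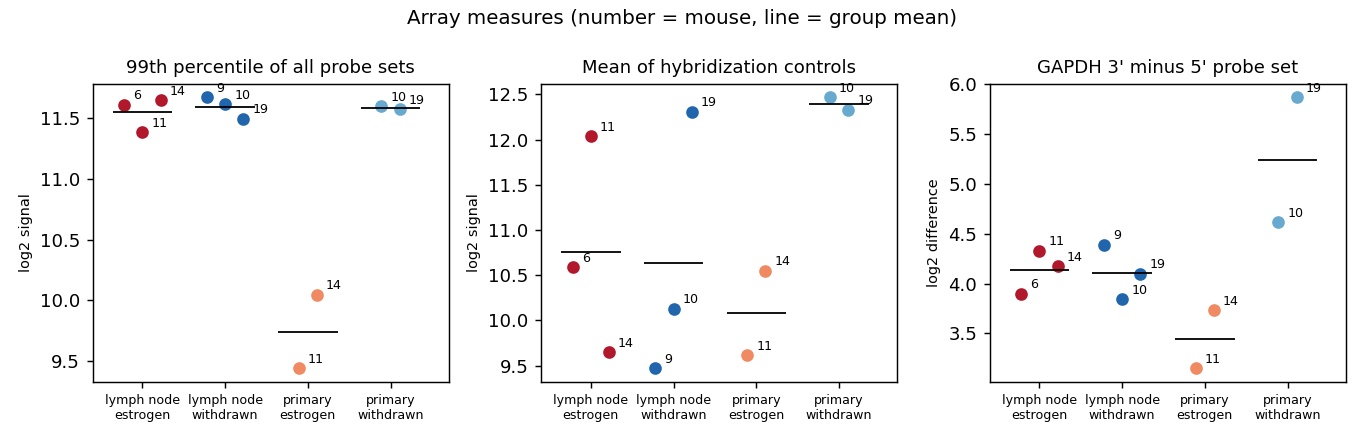
Each point is 1 array, with the 99th percentile of its log2 values, the mean log2 value of the hybridization controls and the log2 GAPDH 3′ minus 5′ difference plotted by group. The 2 estrogen-treated primary tumors reach a 99th percentile of 9.44 and 10.04, below the other 8 arrays.

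Among 12 genes chosen in advance, the estrogen receptor gene ESR1 had a mean log2 value of 8.30 ± 2.53 (SD, n = 3) in lymph node metastases with estrogen and 11.47 ± 0.42 (n = 3) after withdrawal, against 8.15 ± 0.15 (n = 2) and 11.97 ± 0.97 (n = 2) in primary tumors. The estrogen-induced gene GREB1 had 9.33 ± 1.22 with estrogen and 6.47 ± 0.89 after withdrawal in lymph nodes, and 9.69 ± 0.40 and 7.25 ± 0.67 in primary tumors. MYC, a growth-promoting transcription factor, had 7.0 ± 0.70 and 5.05 ± 1.07 in lymph nodes, and 5.53 ± 0.15 and 4.50 ± 0.68 in primary tumors. TFF1, a secreted trefoil peptide, was near the top of the range in lymph nodes in both states (14.10 ± 0.07 and 14.04 ± 0.11) and had 12.36 ± 0.70 and 13.37 ± 0.05 in primary tumors. The cyclin gene CCND1 (10.56 ± 0.16 and 10.52 ± 0.25) and the proliferation marker MKI67 (8.30 ± 0.85 and 8.63 ± 0.45) had like values with and without estrogen in lymph nodes. In primary tumors CCND1 had 9.67 ± 0.33 and 10.21 ± 1.41, and MKI67 had 7.45 ± 0.17 and 7.84 ± 1.37. The luminal genes KRT18 (13.11 ± 0.60 and 13.38 ± 0.07) and GATA3 (11.57 ± 0.36 and 12.32 ± 0.12) were abundant in lymph nodes. In primary tumors KRT18 had 11.50 ± 0.45 and 12.95 ± 0.70, and GATA3 had 10.02 ± 0.54 and 12.71 ± 0.36. The mesenchymal gene VIM stayed between 2.26 and 2.44 in the 4 group means, the leukocyte gene CD74 between 2.92 and 3.59, and the collagen gene COL1A1 between 6.63 and 7.48. The progesterone receptor gene PGR had group means of 2.15 to 2.45. Its mean over the 10 arrays did not reach the filter, so it was not tested.

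**Figure D2:**
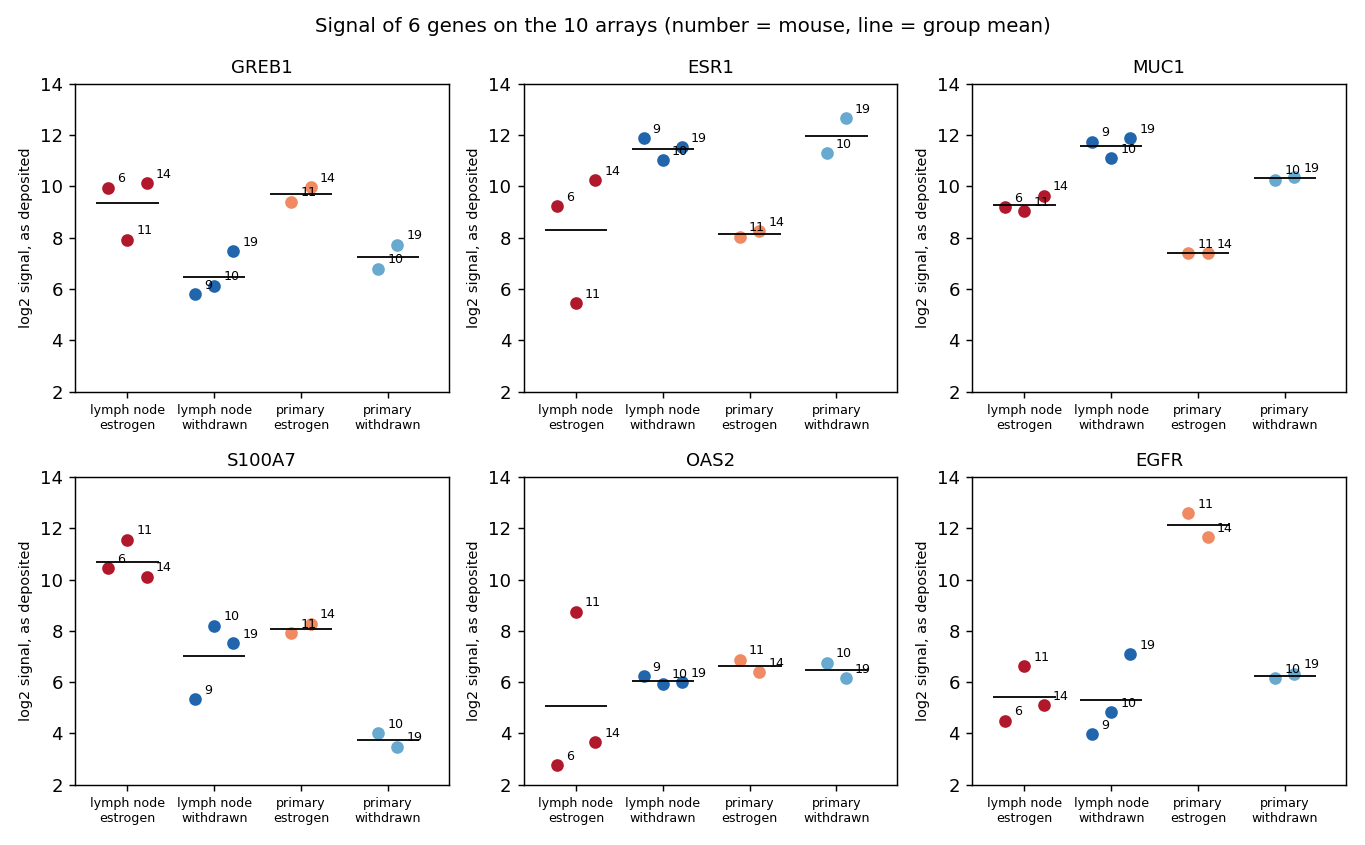
Log2 values of GREB1, ESR1, MUC1, S100A7, OAS2 and EGFR are plotted per array, with mouse numbers beside the dots and a line at each group mean. Mouse 11 with estrogen has the lowest lymph node value of ESR1 (5.44) and the highest of OAS2 (8.75).

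The first comparison asked how the lymph node metastases responded to estrogen. Genes known to be repressed by estrogen in breast cancer cells were lower with estrogen as a group, with 28 of the 31 measured below 0 and a mean log2 difference of −0.74 (camera adjusted p = 2.34e-08, and adjusted p = 3.56e-06 with an estimated correlation). The mean of this list was 6.30 to 6.65 on the 3 estrogen arrays and 7.01 to 7.48 on the 3 withdrawn ones. Among 17169 genes none of its members was called, and adjusted over the list alone 6 fell and 0 rose. They were MUC1, a mucin of the luminal cell surface (−2.29), CCNG2, a cyclin that restrains the cell cycle (−1.98, 4 of its 5 probe sets in that direction), TXNIP, an inhibitor of thioredoxin (−1.83), BLNK (−1.69), LAMB2 (−1.39) and YPEL3 (−1.30). MUC1 stood at 9.28 ± 0.31 (SD, n = 3) with estrogen and 11.57 ± 0.41 (n = 3) after withdrawal. The list stayed called under all 22 alternatives, with means of −0.85 to −0.54, and by fry, a rotation test of the list by itself (adjusted p = 0.0164, where camera gave 2.13e-11 to 0.00011 over the alternatives).

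Luminal epithelial genes were also lower with estrogen in lymph nodes, 25 of 32 with a negative difference and a mean of −0.69 (camera adjusted p = 8.02e-06, and adjusted p = 0.0269 with an estimated correlation), but fry did not call them (adjusted p = 0.0623, where camera gave 4e-07 to 0.00886 over the alternatives). Of the 32, 2 are also on the induced list and 2 on the repressed list, and 21 of the other 28 had a negative difference, with a mean of −0.53. Adjusted over the list alone, MUC1 and the trefoil factor TFF3 (−3.38) fell and 0 rose. Estrogen-induced genes were higher as a group, 50 of 71 with a positive difference and a mean of 0.40 (camera adjusted p = 0.000199), but with adjusted p = 0.484 with an estimated correlation. Adjusted over the list alone 4 rose, GREB1 (2.86, 1 of its 4 probe sets in that direction), the small heat shock protein gene HSPB8 (3.58), RAPGEFL1 (1.97) and ASB13 (1.45), and 2 fell, the receptor tyrosine kinase RET (−2.59) and TFF3. Without the lymph node array of mouse 14 the mean of this list was 0.13 (camera adjusted p = 0.171), and over the other arrays left out in turn it reached 0.73. The other 27 lists were not called, among them interferon response genes (−0.24, adjusted p = 0.356) and mitotic genes (−0.03, adjusted p = 0.738). Both were called without the lymph node array of mouse 11, at −1.28 (adjusted p = 7.97e-25, and adjusted p = 0.00128 with an estimated correlation) and 0.52 (adjusted p = 3.39e-06, and adjusted p = 0.626). That array had the highest interferon and the lowest mitotic mean of its group, so part of these shifts follows from leaving it out. Over 22 alternatives the interferon and mitotic lists lay between −1.33 and 0.40 and between −0.41 and 0.52, with adjusted p up to 0.597 and 0.906. Leaving out 1 array gave calls to other lists as well, such as DNA replication genes without the lymph node of mouse 10 (0.32) or 11 (0.48) and immediate early genes without that of mouse 19 (−0.55), so the lack of a call is no evidence of the lack of a response. On lists not called, genes that passed adjusted over the list alone included the receptor tyrosine kinases ERBB4 (−4.10, 3 of 4 probe sets) and IGF1R (1.17, 4 of 5 probe sets).

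Over all genes, limma called 0 genes in lymph nodes, the smallest adjusted p being 0.0875, with 1002 genes at an unadjusted p below 0.05. The lowest moderated t values, none past the threshold, included the metallothionein MT1F (−2.68 ± 0.32, SE), MUC1 (−2.29 ± 0.26), the glycosyltransferase ST6GALNAC2 (−2.02 ± 0.23), the protease inhibitor CSTA (−2.45 ± 0.36) and the inhibin subunit INHBB (−3.64 ± 0.55). The highest included IL1RN, an interleukin-1 receptor antagonist (1.92 ± 0.23, with 1 of its 3 probe sets in that direction), KRT9 (2.23 ± 0.30) and RAPGEFL1 (1.97 ± 0.34). Without mouse 11, 9 genes passed, 5 higher and 4 lower. Both sides of the hybridization control split gave the repressed list a negative mean, −0.76 for 2 against 2 arrays on the low side and −0.71 for 1 against 1 on the high side, while the induced list had 0.60 and 0.00.

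**Figure D3:**
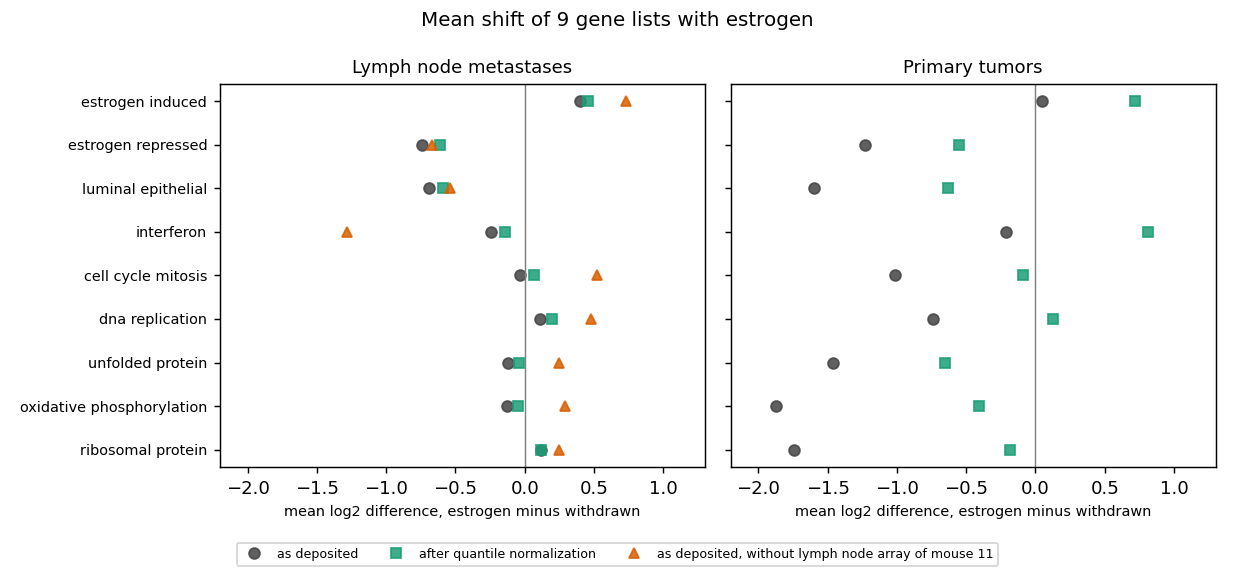
Mean log2 difference, estrogen minus withdrawn, of 9 gene lists in lymph node metastases and primary tumors, as deposited (dots), after quantile normalization (squares) and, for lymph nodes, without mouse 11 (triangles). The repressed list lies at −0.74 in lymph nodes and −1.23 in primary tumors as deposited.

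The same question was asked of the primary tumors. Luminal and estrogen-repressed genes were lower with estrogen. Of 32 luminal genes 10 fell and 0 rose, with a mean of −1.60 (camera adjusted p = 3.99e-06, and adjusted p = 0.0247 with an estimated correlation). The cell adhesion genes CDH1 (−3.13 ± 0.34, 1 of 2 probe sets in that direction) and EPCAM (−3.53 ± 0.49), the luminal transcription factor GATA3 (−2.70 ± 0.35) and MUC1 (−2.92 ± 0.32) were among them. Of 31 repressed genes 8 fell and 0 rose, with a mean of −1.23 (camera adjusted p = 0.00129, and adjusted p = 0.0247 with an estimated correlation), among them CCNG2 (−3.86 ± 0.71, 4 of 5 probe sets), TXNIP (−3.74 ± 0.64) and CASP9 (−2.01 ± 0.34, 1 of 3 probe sets). Adjusted over the list alone, 19 luminal and 12 repressed genes fell. After quantile normalization MUC1 (−1.73), CCNG2 (−2.96) and CASP9 (−1.62) were still called, and CDH1 (−1.40), EPCAM (−1.87), GATA3 (−0.89) and TXNIP (−2.45) were not. The list means were then −0.63 and −0.55, both still called, with adjusted p = 0.00292 and adjusted p = 0.14 with an estimated correlation.

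Genes of translation and mitochondrial respiration were lower too on the deposited scale. Ribosomal protein genes had 26 of 41 members lower and 0 higher (mean −1.74, camera adjusted p = 1.6e-15, and adjusted p = 0.143 with an estimated correlation), with RPL9 at −2.91 ± 0.41. Adjusted over the list alone 37 of them fell. Oxidative phosphorylation genes had 15 of 33 lower and 0 higher (mean −1.87, camera adjusted p = 2.09e-10, and adjusted p = 0.142 with an estimated correlation), with NDUFB3 at −1.93 ± 0.29. These means became −0.18 and −0.41 after quantile normalization and neither list was then called. Unfolded protein response genes (−1.46, adjusted p = 0.00106, and adjusted p = 0.232 with an estimated correlation) included ATF4 (−1.98) and DDIT3 (−2.13) among 7 that fell. Immediate early genes (−1.05, adjusted p = 0.00312, and adjusted p = 0.283 with an estimated correlation) included the phosphatase DUSP1 (−2.27 ± 0.35) and IER3 (−2.94) among 9 that fell. After quantile normalization these 2 means were −0.65 and −0.20 and neither list was called, with adjusted p = 0.0626 and 0.205, where the alternatives reached from 4.84e-05 to 0.0626 and from 0.000127 to 0.286. Estrogen-induced genes had a mean of 0.05 (camera adjusted p = 0.0913), with CCN5 (1.22 ± 0.23) and RAPGEFL1 (1.77 ± 0.42) higher and XBP1 (−2.21 ± 0.31) and CHPT1 (−2.74 ± 0.56) lower. Of the genes named for these lists CCN5 (1.72) was called after quantile normalization, and RPL9 (−1.14), NDUFB3 (−0.10), ATF4 (−0.36), DDIT3 (−1.31), DUSP1 (−1.39), IER3 (−1.20), RAPGEFL1 (2.22), XBP1 (−0.69) and CHPT1 (−1.07) were not. The induced list then had a mean of 0.72 (camera adjusted p = 0.00373, and adjusted p = 0.288 with an estimated correlation), with 3 genes higher and 0 lower, and over its alternatives the mean lay between −0.65 and 0.72. Marker lists of other cell types were called higher with estrogen in the same comparison: myeloid (0.61, adjusted p = 0.00106), T and NK cell (0.23, 0.00812), B cell (0.46, 0.0129), mesenchymal (0.15, 0.0298), MHC class II (0.23, 0.0313), skeletal muscle (0.13, 0.0313) and basal genes (0.59, 0.0466). With an estimated correlation their adjusted p was 0.14 to 0.195, and none was called after quantile normalization (0.0626 to 0.258, where their alternatives gave 0.00045 to 0.286). Among their genes limma called 1 myeloid and 1 basal gene higher and 1 muscle gene lower. Of these 7 lists the myeloid and the T and NK cell lists stayed called whichever array was left out. Both estrogen arrays had the narrower range, so leaving out 1 array could not remove its effect. Camera compares a list with all other genes. In this comparison genes with a mean below 4 had a median difference of 0.11, and genes over 10 had −1.90. Hypoxia (−1.0, 0.00812), cholesterol synthesis (−1.23, 0.0156), mitotic (−1.01, 0.0195), MHC class I (−0.97, 0.0337) and p53 target genes (−0.79, 0.0344) were called lower, with 0.263 to 0.629 with an estimated correlation and 0.454 to 0.967 after quantile normalization, where their alternatives gave 4.79e-06 to 0.967. None of these lower lists stayed called whichever array was left out. Of the 18 lists called in primary tumors, the luminal and the repressed lists were called with an estimated correlation as well.

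Limma called 1342 genes in primary tumors, 151 higher and 1191 lower with estrogen, so that 11.3% were higher. After quantile normalization it called 133 higher and 104 lower, 56.1% higher, and 209 of these 237 genes were among the 1342, with the same sign. The median of all genes was −0.0986 as deposited and 0.0587 after quantile normalization. On the deposited scale genes with a mean over 10 had a median difference of −1.90, and genes below 4 had 0.11. The greatest increases included EGFR, an epidermal growth factor receptor (5.87 ± 0.98), FGFR1, a fibroblast growth factor receptor (5.36 ± 0.61), the antisense transcript SLC38A2-AS1 (5.09 ± 0.36), CARD16 (5.52 ± 0.90) and the glutathione peroxidase GPX3 (4.92 ± 0.88). EGFR had 7 of 8 probe sets in that direction but rested on a pair of them, FGFR1 had 4 of 8 and CARD16 had 3 of 4. Over both sites the FGFR1 probe set used had 2.91 with estrogen and its others −0.67 to 0.19, so its rise rested on that probe set. The greatest decreases included the protocadherin PCDH10 (−5.64 ± 1.36, 2 of 3 probe sets), CSTA (−4.37 ± 0.44), the vesicle transport gene RAB27B (−4.14 ± 0.69), the kinase substrate MARCKS (−4.06 ± 0.54, 4 of 5 probe sets) and the phospholipase PLAAT3 (−4.04 ± 0.58). Of these 10 genes PCDH10 alone was not called after quantile normalization (−5.17, adjusted p = 0.0907, where its alternatives gave 0.00237 to 0.284). Each group held 2 arrays, both estrogen arrays had the narrower range, and they lay on the low side of the hybridization split while both withdrawn arrays lay on the high side, so within these 4 arrays the split went with treatment. With the split as a covariate, 964 genes were higher and 4670 lower, 1277 of the 1342 among them. This covariate was set almost only by the lymph node arrays, mouse 11 included, so the overlap is no check on the primary tumor calls. The count was 5 without the withdrawn primary tumor of mouse 19, 172 without that of mouse 10, 24 and 516 without the estrogen-treated ones of mice 11 and 14, and 711, 520 and 3564 without the lymph nodes of mice 6, 10 and 11. Of 41 called genes named by the rule, SLC38A2-AS1 alone stayed past the threshold whichever array was left out.

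The title of the series speaks of estrogen insensitivity in the metastases, which the difference between the responses addresses. SLC38A2-AS1 (−4.68 ± 0.47, adjusted p = 0.0416, 1 of its 2 probe sets in that direction) and NDRG3, a gene of the N-myc downregulated family (−4.26 ± 0.39, adjusted p = 0.0382), differed in response between sites. After quantile normalization SLC38A2-AS1 (−6.03) was still called and NDRG3 (−5.63, adjusted p = 0.0516) was not. NDRG3 stood at 10.41 ± 0.23 (n = 2) in estrogen-treated primary tumors and at 6.40 ± 0.24 (n = 2) after withdrawal, and at 6.04 ± 0.14 (n = 3) and 6.29 ± 0.37 (n = 3) in lymph nodes. SLC38A2-AS1 stood at 9.23 ± 0.11 and 4.15 ± 0.17 in primary tumors and at 4.08 ± 0.56 and 3.67 ± 0.25 in lymph nodes. A difference in response was not called for estrogen-induced genes (mean difference 0.35, camera adjusted p = 0.806) or estrogen-repressed ones (0.49, adjusted p = 0.409). The induced mean lay between −0.26 and 1.05 over the alternatives, so a difference in either direction was left unresolved. Ribosomal protein genes (1.85, adjusted p = 2.25e-24, and adjusted p = 0.11 with an estimated correlation) and oxidative phosphorylation genes (1.74, adjusted p = 9.89e-13, and adjusted p = 0.114 with an estimated correlation) did, and after quantile normalization their means were 0.30 and 0.36. Of 15 lists called, none was called with an estimated correlation.

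Those 2 genes, both lower, were the only limma calls among 17169, with 1862 genes at an unadjusted p below 0.05. With mouse as a fixed replicate block on the 8 arrays of the 4 mice with both sites, limma called 0 genes, with 1234 at an unadjusted p below 0.05, and NDRG3 had −4.29 and SLC38A2-AS1 −4.51 (both adjusted p = 0.604, against a lowest of 0.00132 over the alternatives). Without the lymph node array of mouse 11 the count was 1543, without the estrogen-treated primary tumor of mouse 14 it was 194, and without each other array it was 0. Across genes the responses of the 2 sites correlated with r = 0.585 (Spearman 0.531), and with r = 0.542 when the lymph node response came from mice 6 and 9, which gave no primary tumor. Genes are not independent replicates. Without mouse 11 in the lymph nodes r was 0.155, and without mouse 9 it was 0.419.

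Over both sites together, luminal and estrogen-repressed genes were lower with estrogen. Of 32 luminal genes 15 fell and 0 rose (mean −1.15, camera adjusted p = 3.32e-07, and adjusted p = 0.0087 with an estimated correlation), and of 31 repressed genes 10 fell and 0 rose (mean −0.99, adjusted p = 1.62e-05, and adjusted p = 0.00135 with an estimated correlation). MUC1 (−2.61 ± 0.20), GATA3 (−1.72 ± 0.22), CCNG2 (−2.92 ± 0.45, 4 of 5 probe sets) and TXNIP (−2.79 ± 0.40) were among them. ESR1 fell by 3.50 (SE 0.82), with 2 of its 6 probe sets in that direction. The probe set used had a mean of 9.95. The others had means of 2.04 to 3.30, near the filter value of 2.311, and differences of −0.01 to 0.37. ESR1 was not called after quantile normalization (−2.69), and 10 of 20 alternatives kept it past the threshold, with values of −4.55 to −0.40. Both lists stayed called after quantile normalization, with means of −0.61 and −0.58, and under all 20 alternatives. Estrogen-induced genes had 7 higher and 4 lower of 71 (mean 0.22, adjusted p = 0.00869, and adjusted p = 0.34 with an estimated correlation), and 9 higher and 1 lower after quantile normalization, where the mean was 0.59. GREB1 (2.63, 3 of 4 probe sets), the carbonic anhydrase CA12 (2.00) and RAPGEFL1 (1.87 ± 0.27) rose, and TFF3 (−2.81) fell. The GREB1 probe set used had a mean of 8.13, and its others had means of 2.24 to 5.67 and differences of −0.02 to 0.09. Without the lymph node array of mouse 14 the induced list was not called (adjusted p = 0.079).

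Among the genes with the greatest increases were SPRR1B, a precursor of the cornified envelope (4.44 ± 0.97), the calcium-binding proteins S100A7 (3.99 ± 0.53) and S100A9 (3.56 ± 0.90), and KRTDAP, a keratinocyte differentiation protein (3.06 ± 0.61). S100A9 is on the myeloid list and the others are on no list. After quantile normalization S100A9 was not called (3.90) and the other 3 were. S100A7 stood at 10.70 ± 0.76 with estrogen and 7.02 ± 1.49 after withdrawal in lymph nodes, and at 8.09 ± 0.26 and 3.75 ± 0.38 in primary tumors. CSTA, a cysteine protease inhibitor, fell by 3.41 (SE 0.28). INHBB (−3.66 ± 0.43), MT1F (−2.96 ± 0.25), the glucocorticoid-induced gene TSC22D3 (−3.62 ± 0.49, 1 of 3 probe sets in that direction) and PCDH10 (−4.54 ± 0.86) also fell. Among growth factor genes ERBB4 fell (−3.19 ± 0.54, 3 of 4 probe sets) and IGF1R rose (1.34 ± 0.19, 4 of 5 probe sets), and both stayed called after quantile normalization (−2.80 and 1.48). Myeloid marker genes had a mean of 0.51 (adjusted p = 0.000725, and adjusted p = 0.144 with an estimated correlation), and the single gene called among them was S100A9, which squamous epithelium also expresses. Ribosomal protein genes had −0.81 (adjusted p = 2.26e-09, and adjusted p = 0.327 with an estimated correlation) and −0.03 after quantile normalization. Their list mean was 12.05 to 12.46 with estrogen and 12.02 to 12.31 after withdrawal in lymph nodes. In primary tumors it was 9.96 and 10.97 against 12.14 and 12.25, so the fall came from the primary tumors. Genes with a mean over 10 had a median difference of −0.1 in lymph nodes and −1.9 in primary tumors. Oxidative phosphorylation (−1.0, adjusted p = 1.57e-07), immediate early (−0.66, 0.00296), hypoxia (−0.63, 0.00869) and unfolded protein response genes (−0.79, 0.00869) were also called lower, with 0.258 to 0.34 with an estimated correlation, and none of these 4 was called after quantile normalization (0.155 to 0.499, where their alternatives gave 5.93e-09 to 0.629).

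Limma called 1376 genes over both sites, 168 higher and 1208 lower, 12.2% higher, against 279 higher and 360 lower, 43.7% higher, after quantile normalization, with 495 genes shared. The count was 15 and 301 without the estrogen-treated primary tumors of mice 11 and 14, and 679 and 232 without the withdrawn ones of mice 10 and 19. It was 542, 2717, 314 and 217 without the lymph nodes of mice 6, 14, 10 and 9. Of the 44 named genes called, CSTA and MUC1 stayed past the threshold whichever array was left out.

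The next comparison set lymph node metastases against primary tumors, averaged over both treatments. SERPINA1, a secreted protease inhibitor, was 4.11 ± 0.52 higher in lymph nodes (1 of its 2 probe sets in that direction), the uroplakin UPK2 3.14 ± 0.25 higher and the actin regulator INF2 2.87 ± 0.30 higher (2 of 3 probe sets). SERPINA1 stood at 8.58 ± 0.55 (n = 3) and 9.07 ± 1.43 (n = 3) in lymph nodes with and without estrogen, and at 4.75 ± 0.68 (n = 2) and 4.67 ± 0.21 (n = 2) in primary tumors. The chemokine CXCL14 was lower in lymph nodes (−2.98 ± 0.30), at 2.82 ± 0.77 and 2.48 ± 0.12 against 6.39 ± 0.38 and 4.86 ± 0.27. These 4 genes were called after quantile normalization too, and whichever array was left out. The caveolin CAV1 (−2.69 ± 0.47) and EGFR (−3.85 ± 0.65, 5 of 8 probe sets) were lower in lymph nodes, and S100A8 (3.00 ± 0.70), S100A7 (2.92 ± 0.55) and MUC1 (1.58 ± 0.21) were higher. EGFR had −6.73 within estrogen-treated mice, so most of its average came from them. Its change with estrogen lay in a pair of probe sets (3.00 and 3.25 over both sites), the others having −0.51 to 0.58. After quantile normalization CAV1 (−3.04) and EGFR (−4.39) were still called, and S100A8 (2.0), S100A7 (2.08) and MUC1 (1.0) were not.

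Mitotic genes were higher in lymph nodes, 40 of 40 with a positive difference, 6 of them called (mean 0.99, camera adjusted p = 0.000104, and adjusted p = 0.508 with an estimated correlation), with CDC20 at 2.44 ± 0.45 and CCNB1 at 1.79 ± 0.31. DNA replication genes (0.76, adjusted p = 0.00143, and adjusted p = 0.516 with an estimated correlation) and hypoxia and glycolysis genes (0.84, adjusted p = 0.000104, and adjusted p = 0.327 with an estimated correlation) had 6 and 9 members higher and 0 lower. After quantile normalization these 3 means were 0.47, 0.28 and 0.35. Among withdrawn arrays on the high side of the hybridization split (1 against 2) they were −0.07, −0.20 and 0.17. Among estrogen arrays on the low side (2 against 2) they were 2.02, 1.55 and 1.47, where both primary tumor arrays had the narrower range. A site difference of these lists in both treatments, apart from the split and the range, was therefore not shown. The hypoxia list's calls included the glycolytic genes ALDOA (2.21), TPI1 (1.89) and LDHA (1.39). Fibroblast and matrix genes were lower (−0.31, adjusted p = 0.00143, and adjusted p = 0.115 with an estimated correlation), with 3 of 17 called, among them COL3A1 (−1.72 ± 0.33, 5 of 6 probe sets). None of the members named here was called after quantile normalization: CDC20 (1.57), CCNB1 (0.94), ALDOA (1.29), TPI1 (0.99), LDHA (0.62) and COL3A1 (−1.89). Without the withdrawn primary tumor of mouse 19 the DNA replication list was not called (0.48, adjusted p = 0.107, against a lowest of 3.5e-07 over the alternatives). Other lists, and abundant genes in general, were higher as well. Ribosomal protein (0.94, adjusted p = 1.15e-11), oxidative phosphorylation (0.96, 4.49e-07), luminal (0.73, 0.00143), cholesterol synthesis (0.91, 0.00143) and immediate early genes (0.77, 0.00334) were called higher too, with 0.247 to 0.327 with an estimated correlation and means of 0.17, 0.23, 0.22, 0.45 and 0.33 after quantile normalization, where the luminal list was not called. Genes with a mean over 10 had a median difference of 0.95, and genes below 4 had −0.01. The former was 1.88 with estrogen and 0.04 after withdrawal, so it came from the estrogen-treated mice. Ribosomal protein list means after withdrawal were 12.02 to 12.31 in lymph nodes and 12.14 and 12.25 in primary tumors. Those of oxidative phosphorylation were 10.19 to 10.64 in lymph nodes and 10.40 and 10.37 in primary tumors. Basal (−0.44, 0.0308) and NF-κB genes (−0.03, 0.0444) were called lower, with 0.115 and 0.327 with an estimated correlation. The basal list was not called after quantile normalization (0.0983), without the lymph node array of mouse 14 (0.0953) or without the estrogen-treated primary tumor of mouse 11 (0.0532), and its alternatives gave 0.00908 to 0.0983. Interferon response genes had a mean of −0.45 (adjusted p = 0.00143, and adjusted p = 0.536 with an estimated correlation), and limma called 0 of its 36 genes. This mean lay between −1.49 and −0.08 over 21 alternatives, with adjusted p from 1.26e-17 to 0.0802. It was −0.11 (adjusted p = 0.069) without the lymph node array of mouse 6, −0.23 (adjusted p = 0.062) without that of mouse 14 and −0.16 (adjusted p = 0.0802) with the hybridization covariate, and the list was then not called.

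Limma called 1400 genes between the sites, 1290 higher and 110 lower in lymph nodes, 92.1% higher, against 22 higher and 40 lower, 35.5% higher, after quantile normalization, with 59 genes shared. The median of all genes was 0.159 as deposited and 0.00995 after quantile normalization. With mouse as a fixed replicate block limma called 0 genes, with 2560 at an unadjusted p below 0.05, and SERPINA1 had 4.23, UPK2 3.17, INF2 2.99 and CXCL14 −2.89 (adjusted p = 0.199 for each). The count was 496, 595, 242 and 3162 without the lymph nodes of mice 6, 9, 10 and 11, and 592, 430 and 341 without the primary tumors of mice 10, 11 and 19.

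Within estrogen-treated mice, RRM2, a subunit of ribonucleotide reductase (3.04 ± 0.40), the secretory pathway gene SAR1B (2.85 ± 0.27, 3 of 4 probe sets), the epithelial transcription factor KLF5 (3.18 ± 0.69) and SERPINA1 (3.85 ± 0.74) were higher in lymph nodes than in primary tumors. EGFR (−6.73, 6 of 8 probe sets), FGFR1 (−5.50, 5 of 8) and CTBP1-DT (−5.29 ± 0.34) were lower. After quantile normalization SAR1B (1.70), EGFR (−7.76), FGFR1 (−6.90) and CTBP1-DT (−6.70) were still called, and RRM2 (1.34), KLF5 (3.07) and SERPINA1 (3.4) were not. Ribosomal protein genes had 35 of 41 members higher and 0 lower (mean 1.86, camera adjusted p = 9.76e-20, and adjusted p = 0.104 with an estimated correlation), with a mean of 2.00 among the 2 against 2 arrays on the low side of the hybridization split and of 0.33 after quantile normalization. Basal and myoepithelial genes were lower (−0.70, adjusted p = 0.00651, and adjusted p = 0.0409 with an estimated correlation), but were not called after quantile normalization (−0.98, adjusted p = 0.0676, where the alternatives gave 0.00086 to 0.0676). Of 17 lists called, the basal list was the only one also called with an estimated correlation. Oxidative phosphorylation (1.83), mitotic (1.48), cholesterol synthesis (1.29), hypoxia (1.21), luminal (1.19), DNA replication (1.18), immediate early (1.16) and unfolded protein response genes (1.10) were also called higher. These are values as deposited, where abundant genes in general were higher. Genes with a mean over 10 had a median difference of 1.88, and of 0.20 after quantile normalization. Fibroblast and matrix (−0.34, adjusted p = 0.000911), interferon (−0.47, 0.00407), MHC class II (−0.20, 0.00496), T and NK cell (−0.11, 0.00508), skeletal muscle (−0.23, 0.0125) and B cell genes (−0.29, 0.0176) were called lower, with 0.0562 to 0.525 with an estimated correlation. Myeloid genes (0.13, 0.00861) were called lower relative to all other genes. Of these 7, fibroblast and matrix and MHC class II genes stayed called whichever array was left out. Limma called 1504 genes, 1341 higher and 163 lower, 89.2% higher, against 16 higher and 71 lower, 18.4% higher, after quantile normalization, with 80 shared. The median of all genes was 0.26 and 0.0235. With mouse as a fixed replicate block the count was 0, with 2501 at an unadjusted p below 0.05 in limma and RRM2 at 2.95 (adjusted p = 0.149). The count was 394, 880 and 3850 without the lymph nodes of mice 6, 10 and 11 and 179 and 833 without the primary tumors of mice 11 and 14.

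After withdrawal, limma called 0 genes between the sites, with 1723 at an unadjusted p below 0.05 and a smallest adjusted p of 0.0643. UPK2 (3.62 ± 0.35, adjusted p = 0.0643) and INF2 (3.65 ± 0.42, adjusted p = 0.0789, 2 of 3 probe sets in that direction) were among the 8 highest t values, and CXCL14 (−2.38 ± 0.42) and the interferon-induced gene RTP4 (−2.67 ± 0.48) among the 8 lowest, both with adjusted p = 0.146. Genes induced by p53 had a mean of −0.36 (camera adjusted p = 0.00578, and adjusted p = 0.938 with an estimated correlation), the only list called as deposited, and −0.84 among the arrays on the high side of the hybridization split, 1 against 2. This list was not called without the withdrawn primary tumor of mouse 10 (−0.06, adjusted p = 0.551) or with array weights (−0.13, adjusted p = 0.0869), and its lowest adjusted p over the alternatives was 5.96e-05. Without the withdrawn primary tumor of mouse 10, mitotic (1.14) and DNA replication genes (0.93) were called instead. Without the lymph node arrays of mice 11 and 14 in turn the count was 42 and 1.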

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

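The splits of the samples were tests planned before the result was seen, and the tests of the narrower range, RNA degradation, the hybridization split, a shared response and single probe sets were chosen after it.

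A pair of genes stood out because their estrogen response differed between the sites in the test of that difference. NDRG3 differed by −4.26 ± 0.39 (SE, limma adjusted p = 0.0382) and SLC38A2-AS1 by −4.68 ± 0.47 (adjusted p = 0.0416, 1 of 2 probe sets in that direction), with both highest in the estrogen-treated primary tumors by group mean. After quantile normalization NDRG3 had −5.63, not past the threshold, and SLC38A2-AS1 −6.03, past it. Of 21 alternatives 9 and 10 kept them past the threshold, with adjusted p from 0.00132 to 0.604 for each. Both stayed called without the lymph node array of mouse 11 or the estrogen-treated primary tumor of mouse 14, and leaving out any other array ended both calls.

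Gene lists stood out in the same test of the difference between the responses. Those whose members were relatively higher with estrogen in lymph nodes were ribosomal proteins (1.85), oxidative phosphorylation (1.74), the unfolded protein response (1.33), mitosis (0.98), p53 targets (0.94), luminal genes (0.91), DNA replication (0.85), MHC class I (0.82), immediate early genes (0.78) and hypoxia (0.73). Those relatively lower were skeletal muscle (−0.44), growth factor signalling (−0.32), MHC class II (−0.29), T and NK cell markers (−0.22) and myeloid markers (−0.19). With an estimated correlation the lowest camera adjusted p among these 15 was 0.064. After quantile normalization ribosomal proteins (0.30), oxidative phosphorylation (0.36), the unfolded protein response (0.61), p53 targets (0.36), skeletal muscle (−0.59) and growth factor signalling (−0.75) were still called, and luminal genes had 0.04. Without each array in turn 5 of the 15 lists stayed called.

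Probe sets without a gene name, which no comparison used, also gave calls: 95 of 9583 changed with estrogen over both sites, 32 higher and 63 lower, and 54 of 9565 after quantile normalization, 33 higher and 21 lower.

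A separate pattern was the excess of lower calls in estrogen-treated primary tumors, 1191 of 1342. Degraded RNA would raise the GAPDH 3′ minus 5′ difference, which differed from withdrawn primary tumors by −1.8 on the log2 scale. This value does not decide, because the narrower range of the estrogen-treated primary tumor arrays can also lower an abundant 3′ signal. Their GAPDH 3′ values were 9.757 in mouse 11 and 10.784 in mouse 14. Withdrawn primary tumors had 11.985 in mouse 10 and 11.581 in mouse 19, so degradation stays open. The low side of the hybridization split did not narrow the range by itself, since its lymph node arrays had 99th percentiles of at least 11.61. A response of abundant transcripts shared by both sites was argued against by the genes with a mean over 10, taken by level and not by their call, whose median difference was −1.90 in primary tumors and −0.10 in lymph nodes. The 1191 genes had −2.13 and −0.37, with −0.19, −0.90 and −0.03 for mice 6, 11 and 14, but as they were picked by their call in primary tumors the first value is inflated. The narrower range of the 2 arrays could account for most of it, as 43.9% of the calls were lower after quantile normalization, 104 of 237. A true fall of abundant transcripts in these 2 tumors alone, which quantile normalization would also remove, was not tested and stays open.

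A further pattern was the small number of very large increases in estrogen-treated primary tumors, such as EGFR and FGFR1. If these were signal of single probe sets, for example through cross-hybridization, the other probe sets of the genes would rarely rise. Of 270 such probe sets 7.78% rose by at least 1 log2 unit, and 36.5% of the 1777 other probe sets of the lower calls fell by as much. After quantile normalization the shares were 15.5% of 284 and 25.4% of 118, so the test did not decide. Other probe sets of a gene can also read other transcripts or lie near the floor, which keeps it open, and no biological explanation was tested.

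For 3 against 3 lymph node arrays the 10 splits are too few to exclude chance. The real split gave 0 genes in limma, with 1002 at an unadjusted p below 0.05, and the highest other split gave 0. For estrogen over both sites the 6 splits of the mice are also too few, with 1376 genes for the real one and 7 for the highest other. For lymph node against primary tumor 2 of 100 splits gave at least 1400 genes, the real one included. The other, with 2183 genes, kept the 4 primary tumors together and put the lymph node arrays of mice 11 and 19 with them, so it parted 2 of the 4 pairs and overlapped with the real split. Its withdrawn arrays were parted exactly as by the hybridization control split. Its estrogen arrays were parted as on the first principal component (87.1, 93.8 and 87.8 against −15.8 and −51.1). This split thus followed array measures rather than site, and whether they account for its count was not tested. With mouse as a fixed replicate block limma called 0 genes between the sites, with 2560 at an unadjusted p below 0.05. Among the 16 splits that parted all 4 pairs of arrays from 1 mouse, the highest other count was 231, and 16 splits are too few for a share below 0.05.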

How the results depend on the processing

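The values for quantile normalization without the lymph node array of mouse 11, for the hybridization control covariate and for the low-side lymph node arrays come from alternatives chosen after seeing the data. The number of called genes moved with the scale of the arrays, array weights, the hybridization covariate, single arrays and, between the sites, the fixed replicate block, and the cause was not tested except where named. Of the tests of gene lists under the alternatives, 1513 kept their direction and side of the threshold, 191 were weaker, 32 stronger, 22 reversed, and 16 had the other sign with no call either way. Of those of named genes 5107 did so, 862 were weaker, 242 stronger, 2 reversed, and 115 had the other sign with no call either way. Leaving out the random mouse block changed none of the 7 counts by over 1.5 times. As the arrays give no detection call, changes of genes near the lowest values, where signal over background is small, cannot be resolved.

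For estrogen in lymph nodes (0 genes), taking the mean of a gene's probe sets gave 2 genes, array weights (fitted gene by gene, since the REML fit did not converge) 535, quantile normalization without mouse 11 7, the hybridization covariate 2, and an unadjusted p with a 2-fold change 560. Leaving out 1 array gave 0 to 9. For primary tumors (1342), the mean of probe sets gave 694, quantile normalization 237, array weights 3496, only the 2 groups compared 3685, the hybridization covariate 5634 and the unadjusted threshold 3715, and leaving out 1 array gave 5 to 3564. For the difference of responses (2), no filter gave 4, the mean of probe sets 1, quantile normalization 1, median centring 4, the trend and robust option 0, array weights 1301, the fixed replicate block 0, quantile normalization without mouse 11 38, the covariate 3390 and the unadjusted threshold 1673, and leaving out 1 array gave 0 to 1543. Both counts of 0 are from limma, with 1801 genes at an unadjusted p below 0.05 for the trend option and 1234 for the block.

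For lymph node against primary tumor with estrogen (1504), the mean of probe sets gave 843, quantile normalization 87, array weights 5583, the fixed replicate block 0 in limma (2501 at an unadjusted p below 0.05), quantile normalization without mouse 11 471, the covariate 4491 and the unadjusted threshold 3151, and leaving out 1 array gave 179 to 3850. After withdrawal (0), the mean of probe sets gave 1, the trend and robust option 3, array weights 263, quantile normalization without mouse 11 1, the covariate 1078 and the unadjusted threshold 976, and leaving out 1 array gave 0 to 42. Over both treatments (1400), the mean of probe sets gave 902, quantile normalization 62, the trend and robust option 912, array weights 5056, the fixed replicate block 0 in limma (2560 at an unadjusted p below 0.05), quantile normalization without mouse 11 379 and the covariate 2651, and leaving out 1 array gave 242 to 3162. The fixed block uses 8 of the 10 arrays and spends a coefficient on each mouse. For estrogen over both sites (1376), the mean of probe sets gave 773, quantile normalization 639, array weights 4280, quantile normalization without mouse 11 845, the covariate 5517 and the unadjusted threshold 2620, and leaving out 1 array gave 15 to 2717.

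The estrogen-induced list in lymph nodes, with a mean of 0.40, was not called with an estimated correlation (adjusted p = 0.484) or by fry (adjusted p = 0.605), where its mean is the same 0.40, and leaving out 1 array gave 0.13 to 0.73. In primary tumors (0.05) its mean was 0.04 with a filter at the median of all probe sets, 0.13 with the mean of probe sets, 0.72 after quantile normalization with or without mouse 11, −0.02 after median centring and −0.65 with the covariate, and −0.07 to 0.17 without 1 array. In the difference of responses (0.35) it was −0.26 after quantile normalization, −0.05 without mouse 11 as well, and 0.08 to 0.69 without 1 array. The correlation of the responses (0.585) was 0.192 after quantile normalization without mouse 11 and 0.155 to 0.688 without 1 array.

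Signs turned as follows. Quantile normalization turned MHC class I genes to 0.22 in primary tumors and −0.27 in the difference of responses, and to 0.20 and −0.69 without mouse 11. It turned hypoxia genes to −0.07 in the difference of responses, p53 targets to −0.25 over both treatments (−0.32 without mouse 11), and myeloid genes to −0.03 in estrogen-treated mice (−0.24 without mouse 11), where leaving out 1 array gave −0.07 (mouse 11) to 0.30. It also turned GATA3 between the sites with estrogen, to −0.22 (−0.11 without mouse 11), and without mouse 11 it turned ribosomal protein genes over both sites to 0.02. Interferon genes with estrogen turned to 0.21 with the fixed replicate block, and leaving out 1 array gave −1.48 (mouse 11) to 0.21 (mouse 6). Skeletal muscle genes in primary tumors turned to −0.12 with the filter at the median. The hybridization covariate turned the induced list over both sites to −0.13. NF-κB genes between the sites turned to 0.10 with the mean of probe sets, 0.01 with the fixed block, 0.02 with the covariate, and leaving out 1 array gave −0.16 to 0.06, above 0 without lymph node mouse 6 (0.02), 14 (0.06) or 19 (0.01) or primary tumor mouse 10 (0.03). The fixed replicate block also ended the call of growth factor signalling genes in the difference of responses (−0.23, adjusted p = 0.0995), and it changed the call of no list other than those named here.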

Other observations

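The tests of the lymph node array of mouse 11 were chosen after the result was seen, while leaving out each array in turn was planned.

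Without the lymph node array of mouse 11, interferon response genes were lower with estrogen in lymph nodes, 33 of 36 with a negative difference and a mean of −1.28 (camera adjusted p = 7.97e-25, and adjusted p = 0.00128 with an estimated correlation), against −0.24 (adjusted p = 0.356) with it. In its group that array had the highest interferon and the lowest mitotic and induced list means. Part of these shifts therefore follows from leaving it out, and their p-values are no independent support. On the low side of the hybridization split the interferon mean was −1.24 (2 against 2 arrays). On the high side, where mouse 11 lies, it was 1.75 (1 against 1). The antiviral gene OAS2 (−2.84 ± 0.33, SE, 2 of 3 probe sets in that direction) and XAF1 (−2.69 ± 0.30) were called. Estrogen-induced genes were higher, 54 of 71 and a mean of 0.73 (adjusted p = 1.46e-10, and adjusted p = 0.00145 with an estimated correlation), and estrogen-repressed genes were lower (−0.67, adjusted p = 6.23e-11, and adjusted p = 0.000156 with an estimated correlation). Mitotic genes had 39 of 40 with a positive difference (0.52, adjusted p = 3.39e-06, and adjusted p = 0.626 with an estimated correlation). The other 7 of the 9 called genes were LINC00052 (5.84 ± 0.41), the neuropeptide Y receptor NPY1R (4.37 ± 0.33), the amine oxidase MAOB (3.76 ± 0.38, 1 of 2 probe sets), TSKU (2.92 ± 0.29), the lysyl oxidase LOXL4 (2.17 ± 0.24, 1 of 2 probe sets), ST6GALNAC2 (−1.82 ± 0.21) and MT1F (−2.39 ± 0.29). After quantile normalization OAS2 (−2.67, adjusted p = 0.051), LOXL4 (2.01, adjusted p = 0.0658) and MT1F (−2.31, adjusted p = 0.0753) had like differences but were no longer called, and the adjusted p of the other 6 lay between 0.00898 and 0.0468. With all arrays limma called 0 genes here, with 1002 at an unadjusted p below 0.05.

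Several marker lists were not called with estrogen over both sites. Camera did not call endothelial (0.07, adjusted p = 0.0582), adipocyte (−0.02, adjusted p = 0.333), lymph node stroma (−0.04, adjusted p = 0.38), skeletal muscle (−0.09, adjusted p = 0.251), basal (0.33, adjusted p = 0.0795), fibroblast (0.08, adjusted p = 0.154) or MHC class II genes (0.09, adjusted p = 0.138). B cell (0.29, adjusted p = 0.00869), T and NK cell (0.12, adjusted p = 0.0255) and mesenchymal genes (0.16, adjusted p = 0.0106) were called, with adjusted p = 0.184, 0.239 and 0.184 with an estimated correlation. Among signalling lists it did not call NF-κB (0.19, adjusted p = 0.0766), p53 (−0.32, adjusted p = 0.313), apoptosis (−0.35, adjusted p = 0.154), growth factor (−0.03, adjusted p = 0.333), estrogen receptor coregulator (−0.59, adjusted p = 0.154), invasion (−0.30, adjusted p = 0.596) or MHC class I genes (−0.56, adjusted p = 0.0682). Leaving out 1 array gave calls for MHC class I genes (−0.73 without lymph node mouse 11 or withdrawn primary tumor mouse 19), NF-κB genes (0.23 and 0.26 without lymph node mouse 6 or 14) and endothelial genes (0.07 and 0.09 without lymph node or primary tumor mouse 19). Cholesterol synthesis genes were called (−0.85, adjusted p = 0.00869, and adjusted p = 0.34 with an estimated correlation), but did not stay called whichever array was left out.

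The lymph node array of mouse 11 stood apart from the other estrogen-treated lymph nodes. Its interferon list mean was 8.87, against 5.50 in mouse 6 and 6.00 in mouse 14, and its ESR1 value was 5.44. A change of the whole mouse would also raise the interferon list in its primary tumor, where mouse 11 exceeded mouse 14 by 0.04 (7.25 and 7.21). These values argue against it only weakly. They rest on 1 array per mouse, both with the narrower range, and the primary tumor of mouse 14 itself lay above its lymph node. An exchange with a withdrawn lymph node was argued against by ESR1, whose difference from the lowest withdrawn lymph node was −5.58. Host leukocytes in the capture could raise interferon genes, and the T and NK cell list was 0.08 above the higher of the other 2 arrays, the B cell list 0.13 and the myeloid list 0.44. Of 5 single markers CD3D was above it (3.01, 0.53), and CD74 (2.54, −0.75), CD79A (5.19, −1.33), TYROBP (2.07, −0.32) and HLA-DRA (3.12, −0.13) were below. This did not decide, because a human array reads mouse RNA only by cross-hybridization, laser capture would leave out most such cells, and S100A8 and S100A9 on the myeloid list are also epithelial genes.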
